A study of Mus musculus with 41 samples.

How the data were processed

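Polyadenylated RNA was sequenced in bulk from B cells sorted from mouse spleen into 6 subsets. The 41 libraries fall into 12 groups: wild type (wt) or the mutant genotype, labelled 1Mek2, in each subset. Per the labels, the mutant mice carried floxed Mek1 alleles, a single intact Mek2 allele and the Vav1-iCre transgene, which is active in blood cells. Mek1 is the gene Map2k1 and Mek2 is Map2k2. Map2k2 was not lower in the libraries of this genotype. Map2k1 was lower without overlap only in age-associated B cells. Reads on exons pointed the other way there, mostly through a single library of this genotype. The text therefore writes "libraries labelled 1Mek2".

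Submitters' processing notes list Trim Galore 0.6.5, STAR 2.7.11a, featureCounts 2.0.3 and the genome build GRCm39. The authors deposited raw read counts for 50763 genes, each counted as 1 interval from gene start to gene end for 50760 of them, so reads on introns were included (gene-span counts). The authors also deposited TPM (transcript abundance) for 41075 entries, of which 41069 were in the count table and 6 named no gene. Multiplying each TPM value by its exonic length gave whole multiples of a single constant per library for 100% of the values checked (tolerance 0.02), and dividing by that constant gave reads on exons. How reads on overlapping genes were assigned is not stated; 1849 genes were at 0 in every count column with a mean of at least 10 exon reads, among them immunoglobulin genes and Xist. Symbols and coordinates are those of the count table (GRCm39). Of the symbols, 46107 were matched to a RefSeq table of the older build GRCm38, used for names only.

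Total gene-span counts per library ran from 7883989 to 34925667, and exon reads from 7897848 to 29204625. Reads without molecular identifiers are not independent molecules, so precision from depth covers counting error only.

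Groups were taken from the labels. The animal was read from the number in each library name, which gave 16 animals. By exon reads of the Y-linked gene Ddx3y, animals 562 (wt), 634 and 654 (both labelled 1Mek2) were male, with 12.1 to 85.8 CPM. No other animal had more than 0.0777. Animal 562 gave wt libraries, and 634 and 654 gave libraries labelled 1Mek2, of ABC, Follicular and MarginalZone. Animal 654 also gave a Plasma library. Sex was thus uneven between genotypes in these subsets, and it was not a term in any fit. Animal 565 had an Immature library labelled 1Mek2 and a GC library labelled wt, and both library names read Mek1ff; its Immature library was left out of the comparisons and its GC library kept as wt. The age-associated B cell (ABC) gate is not stated in the labels. The values of the ABC, Follicular, MarginalZone and Plasma libraries split into 2 types, 7 of type 1 and 19 of type 2. Within these subsets the types followed the animal and not the genotype. None of the 8 animals with at least 2 such libraries had both types. Immature and GC libraries were given no type. On the index of genes that set the types they ran from 1.96 to 3.94. Type 1 ran from 2.95 to 3.81 and type 2 from -3.48 to 0.70. Animal 323 had 3.09 in Immature and 3.46 in GC, but -2.25 in MarginalZone and -0.31 in Plasma. These types were found in the values and are not in the labels.

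Each genotype comparison (libraries labelled 1Mek2 minus wt, within a subset) and each comparison of a subset with Follicular in wt used edgeR 4.0.16: TMM scaling, filterByExpr, robust dispersions, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The average genotype effect over the 6 subsets used limma 3.58.1 with voom and the animal as a random block. The genotype by subset interaction was an edgeR test with 5 degrees of freedom over all 12 groups. All tests were two-sided. Standard errors of log2 fold changes were derived from the test statistic. CPM are TMM-normalised gene-span counts relative to library size unless exon reads are named; those of Map2k1 and Map2k2 in single libraries were scaled over all libraries, the others within their comparison.

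The 33 gene lists were written before the data were examined: 20 of programs and B cell identities, 10 of other cell types and 3 of RNA quality or sex. Lists of programs and identities with at least 5 tested members were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. camera with an estimated correlation was an alternative. fry was also run, which tests for any change of a list and not against other genes. Neither camera nor fry took gene span into account. Sums of CPM over lists of other cells were compared by exact permutation tests; 3 libraries against 3 cannot give a p below 0.1.

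Named genes followed a rule set before the data were examined. It took Map2k1 and Map2k2, then per genotype comparison the 6 called genes with the largest positive and the 6 with the largest negative log2 fold change. Those needed a mean of at least 5 CPM and no overlap between groups; segments of immunoglobulin and T cell receptor genes, and provisional symbols, were left out. Per list it took up to 4 called members with the smallest p, or, where none was called, up to 2 members with the highest mean CPM as values. Per subset comparison it took up to 4 members of the subset's own list and 2 follicular genes. For the average and the interaction it took the 8 genes with the smallest p under the same limits on CPM and symbols. Members of the ERK list in Follicular libraries, immunoglobulin constant genes in exon reads, Sva, Slc15a2, neutrophil genes and interferon-inducible genes of chromosome 1 in the average were chosen after their values were seen.

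The tests were run on simulated counts with the dispersions fitted to these libraries and 100 genes changed per fold size. At 4-fold they recovered 51% in Immature, 51% in GC, 38% in Follicular, 2% in MarginalZone, 2% in Plasma and 0% in ABC; at 2-fold, at most 2% in any genotype comparison. With a dispersion of 0.05 they recovered 100% of 4-fold changes in each.

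Alternatives fixed before the data were examined were RLE size factors, no or a stricter filter on low counts, DESeq2 1.42.0, limma voom, limma-trend on log2(TPM + 1), a fit on all libraries together, a replicate or animal block, omission of immunoglobulin or sex-linked genes, either label for animal 565, and leaving out each library or animal in turn. Alternatives chosen after seeing the data were exon reads, a term for the library type, type 2 libraries only, Follicular of type 1 only, a term for background reads on long neuronal genes, a term for each library's exon share, and omission of ABC_wt replicates 1 and 2 together. R 4.3.3 and Python 3.11.15 were used.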

Results

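RNA from 6 sorted splenic B cell subsets was measured in mice of 3 to 5 months to ask what the loss of Mek1 with a reduced dose of Mek2 changes in each. MEK1 and MEK2 are the kinases that activate ERK. The subsets were Immature (B220+CD93+CD138-), germinal center (GC; GL7+FAS+), ABC, Follicular (CD21+CD23+), MarginalZone (CD21+CD23-) and Plasma (B220+CD138+). There were 3 wt libraries and 4 labelled 1Mek2 of Immature cells, 4 and 4 of GC, 3 and 3 of ABC, 4 and 4 of Follicular, 3 and 3 of MarginalZone, and 3 and 3 of Plasma. The total count per library ran from 17036755 to 23075231 in Immature, 14819446 to 25326853 in GC, 19157012 to 28461762 in ABC, 18875222 to 33450184 in Follicular, 14060655 to 34925667 in MarginalZone and 7883989 to 18516751 in Plasma.

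The targeted genes were read first in every library. Map2k1 (chromosome 9, 64093066 to 64160887) differed between genotypes by a log2 fold change of -0.33 ± 0.37 (SE) in Immature, 0.12 ± 0.33 in GC, -1.97 ± 0.81 in ABC, -0.09 ± 0.25 in Follicular, -0.27 ± 0.47 in MarginalZone and 0.10 ± 0.40 in Plasma. Map2k2 (chromosome 10, 80941749 to 80960531) was not lower in the libraries labelled 1Mek2: its log2 fold changes were 0.58 ± 0.40, 0.89 ± 0.33, 1.58 ± 1.12, 0.73 ± 0.39, 1.26 ± 0.49 and 0.93 ± 0.34 in the same order. Neither gene passed the test in a single subset, with adjusted p from 0.199 upward for Map2k1 and from 0.244 upward for Map2k2. Every library labelled 1Mek2 had more Map2k2 than every wt library in GC, MarginalZone and Plasma. Map2k1 was below every wt library in all 3 ABC libraries labelled 1Mek2 (216 to 272 against 429 to 1256 CPM) and in 2 of 3 Immature ones; of 4 Follicular libraries, 3 were below when scaled over all libraries and 1 when scaled within the comparison. In exon reads its log2 fold changes were -0.56 ± 0.27, 0.14 ± 0.24, 2.48 ± 1.60, -0.12 ± 0.73, -1.73 ± 0.74 and -0.44 ± 0.69 in the order above, without a call. The ABC value rested mostly on ABC_1Mek2 replicate 3, of library type 1, at 207 exon CPM (20.5 and 20.9 in replicates 1 and 2). In Follicular libraries exon CPM of Map2k1 were 223 and 233 in type 1 and 34.0 to 54.5 in type 2. The types were uneven between genotypes in ABC, MarginalZone and Plasma. Averaged over the subsets, Map2k2 was higher by 1.10 ± 0.30 (limma, adjusted p = 0.0182), and Map2k1 differed by -0.32 ± 0.18 (adjusted p = 0.34). The adjusted p of Map2k2 was 0.108 without animal 358, 0.0534 without animal 323, 0.0533 without animal 654 and 0.0982 in exon reads. A floxed allele can lose an exon and still give reads over the rest of the gene, and counts per exon were not analysed here.

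**Figure D1:**
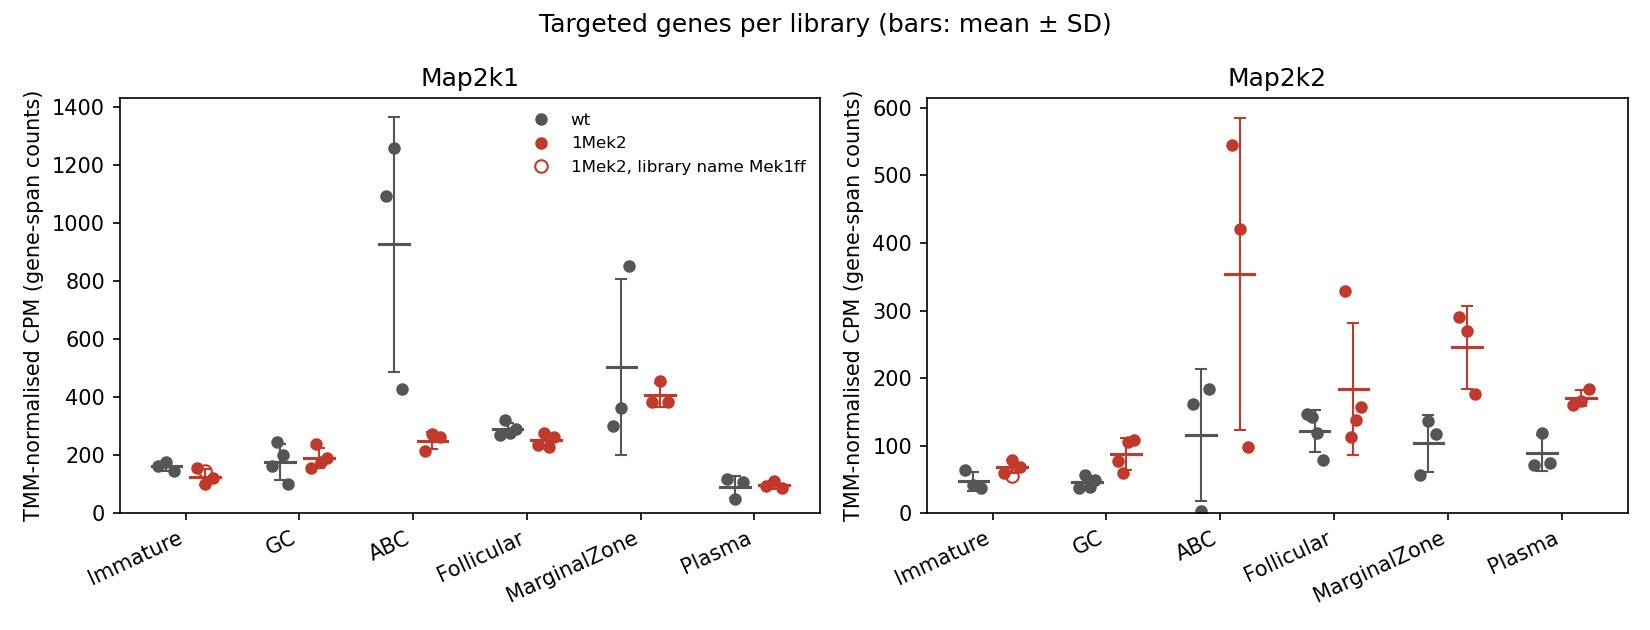
TMM-normalised CPM (gene-span counts) of Map2k1 and Map2k2 in each library by subset, grey for wt and red for libraries labelled 1Mek2, with mean and SD; the open point is the Immature library whose name reads Mek1ff. In Plasma, Map2k2 ran from 72.2 to 120 CPM in wt and from 161 to 184 in libraries labelled 1Mek2.

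In wt mice, each subset was compared with Follicular cells to see whether it carried its identity genes. Immature cells had more Cd93, the marker they were sorted on (log2 fold change 3.42 ± 0.50), more Myb, a transcription factor of progenitors (3.81 ± 0.68), and more Dntt, the terminal transferase of immature lymphocytes (6.37 ± 1.26). Erg was higher by 3.22 ± 0.94, and Il4ra and Cr2, the genes of an interleukin-4 receptor chain and of CD21, were lower by -1.32 ± 0.35 and -1.09 ± 0.29. Of 8 tested immature identity genes 5 rose, and 5 when adjusted over the list alone; the list itself missed the threshold (adjusted p = 0.0987). In all, 7938 genes passed (6498 higher in Immature, 1440 lower; n = 3 against 4). RLE scaling moved the median of all genes by -0.17 (log2). In exon reads 999 genes passed. The Immature wt libraries had reads on 31345 to 35644 genes and 1653 ± 958 CPM of long neuronal genes, against 19404 to 22836 and 37.6 ± 12.8 in Follicular wt, and 2597 of the 7938 genes had a mean of at least 5 CPM.

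GC cells had 191-fold more S1pr2, a receptor that keeps cells in germinal centers, with 1.16 ± 0.16 CPM in Follicular and 223 ± 57.7 in GC libraries (mean ± SD, n = 4 and 4). Gcsam, a germinal center signalling adaptor, rose from 0.0807 to 512 CPM, Mybl1 by a log2 fold change of 8.25 ± 0.61 and Plxnb2 by 5.23 ± 0.40. S1pr1, which directs exit from lymphoid tissue, fell from 522 ± 189 to 32.6 ± 25.8 CPM, and Il4ra fell by 2.07 ± 0.36. Of 13 germinal center identity genes 11 rose (11 adjusted over the list alone), and the list rose against all genes (adjusted p = 1.31e-36; adjusted p = 0.000263 with an estimated correlation). A total of 3923 genes passed, 2279 up and 1644 down. Without Follicular_wt replicate 4 the count was 7025, without GC_wt replicate 3 it was 6374, and with Follicular_wt replicate 4, the only wt Follicular library of type 1, as the sole reference it was 431.

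ABC cells had more Itgax, the gene of CD11c (96.3 ± 8.60 CPM against 0.348 ± 0.26 in Follicular, n = 3 and 4), more Zeb2, a transcription factor of this subset (log2 fold change 5.07 ± 0.58), more Lgals1 (5.41 ± 0.60) and more Fcrl5 (4.46 ± 0.67). Cr2 was lower by -2.10 ± 0.51, and S1pr1 was higher by 2.01 ± 0.42. Of 13 age-associated identity genes 5 rose (7 adjusted over the list alone); the list rose (adjusted p = 5.03e-05), though not with an estimated correlation (adjusted p = 0.177 with an estimated correlation). Summed within the genotype comparisons, these libraries held 2764 ± 834 CPM of plasmacytoid dendritic cell genes, 449.8 ± 173 of dendritic cell genes and 255 ± 296 of natural killer cell genes, against 124 ± 39.1, 35.6 ± 5.95 and 14.0 ± 8.48 in Follicular. In all, 2903 genes passed (1712 up, 1191 down), 1206 with the animal as block and 1363 among type 2 libraries, which is the set without Follicular_wt replicate 4. Leaving out Follicular_wt replicate 1, 2 or 3 gave 927, 966 or 1150, leaving out ABC_wt replicate 3 gave 6427, and RLE scaling moved the median of all genes by 0.23 (log2).

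MarginalZone cells had more Fcrl5 (log2 fold change 3.87 ± 0.37), more Myof (5.99 ± 0.58) and more Asb2 (4.19 ± 0.60), and less Fcer2a, the gene of CD23 that the gate excludes (-5.25 ± 0.84). S1pr3, a receptor that holds cells in the marginal zone, went from 11.1 ± 9.36 to 134 ± 47.3 CPM (mean ± SD, n = 4 and 3), with an adjusted p of 0.055. Of 13 marginal zone identity genes 3 rose, and 11 when adjusted over the list alone; the list rose (adjusted p = 7.86e-30; adjusted p = 0.00383 with an estimated correlation). In all, 50 genes passed (40 up, 10 down), 116 with the animal as block and 263 with a term for library type. Leaving out 1 of Follicular_wt replicates 1, 2 and 3 or MarginalZone_wt replicate 1 gave 12, 11, 11 or 13 genes, and exon reads gave 15.

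Plasma cells had more Jchain, which joins secreted antibodies (10451 ± 4080 CPM against 8.28 ± 8.08 in Follicular, n = 3 and 4), more Prdm1, the transcription factor that drives plasma cell differentiation (log2 fold change 5.54 ± 0.75), more Derl3 (5.56 ± 0.39) and more Creld2 (4.28 ± 0.40). Cr2 and Bank1, of mature B cell signalling, were lower by -6.08 ± 0.41 and -5.31 ± 0.41. Of 16 plasma cell identity genes 14 rose (15 adjusted over the list alone), and the list rose (adjusted p = 8.96e-14), though not with an estimated correlation (adjusted p = 0.189 with an estimated correlation). A total of 2754 genes passed, 1893 up and 861 down. Without Follicular_wt replicate 4 the count was 4616. Summed within the genotype comparisons, the wt Plasma libraries also held 5586 ± 2273 CPM of T cell genes and 2958 ± 1607 of neutrophil genes, against 137 ± 66.2 and 0.602 ± 0.72 in Follicular.

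In Immature cells, genes of cell division, antibody secretion and the germinal center were higher in the libraries labelled 1Mek2 (n = 3 and 3). All 24 cell cycle genes had positive changes, with a median log2 fold change of 1.96, and 10 of them rose (19 adjusted over the list alone). In exon reads 0 were called by edgeR (median 1.79), with the background term 0 (1.38) and with animal 565 as 1Mek2 0 (1.60). Without Immature_wt replicate 1 the median was 3.08. Among them were Cdk1, the kinase that drives mitosis, from 20.8 ± 15.6 to 106 ± 26.2 CPM (mean ± SD), Tyms, which makes thymidylate for DNA synthesis (log2 fold change 2.10 ± 0.42), Aurka (1.93 ± 0.47) and Mcm5 (1.78 ± 0.43). The list rose (adjusted p = 2.96e-37), though not with an estimated correlation (adjusted p = 0.24 with an estimated correlation).

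Of 16 plasma cell identity genes 4 rose (10 adjusted over the list alone): Xbp1, the transcription factor of secretory cells, from 251 ± 148 to 996 ± 395 CPM, Creld2 (1.98 ± 0.40), Ell2, which favours secreted immunoglobulin mRNA (1.90 ± 0.40), and Derl3 (2.59 ± 0.64). Of 16 unfolded protein response genes 5 rose (12 adjusted over the list alone), among them the endoplasmic reticulum factors Sdf2l1 (1.83 ± 0.40), Manf (1.61 ± 0.39), Sel1l (1.51 ± 0.38) and Sec61a1 (1.53 ± 0.39). Of 13 germinal center genes Neil1, a DNA glycosylase (2.35 ± 0.41), and Fas, the death receptor used to sort GC cells (1.75 ± 0.41), rose (6 adjusted over the list alone). These 3 lists rose with adjusted p of 2.73e-14, 8.82e-14 and 8.41e-13, and each missed the threshold with an estimated correlation (adjusted p = 0.24 with an estimated correlation). Immunoglobulin took 2.17 ± 0.13% of exon reads in wt and 4.08 ± 1.34% in libraries labelled 1Mek2 (exact permutation p = 0.1, the smallest this design allows). Stromal and endothelial genes summed to 345 ± 50.4 and 219 ± 53.5 CPM (exact permutation p = 0.1) and erythroid genes to 139 ± 27.6 and 71.5 ± 39.6 (0.2). The exon share was 81.7 ± 6.04 and 89.9 ± 3.86% (0.2), and reads on long neuronal genes summed to 1653 ± 958 and 856 ± 612 CPM (0.3).

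Also in Immature cells, the lists of glycolysis (Tpi1 1.74 ± 0.39), cholesterol synthesis (Fdps, 41.5 ± 6.12 to 117 ± 38.1 CPM), Myc targets, age-associated identity (Lgals1 1.95 ± 0.51), antigen presentation and the Bcl2 family rose, with adjusted p of 9.19e-10, 1.31e-07, 7.89e-06, 1.39e-05, 0.0034 and 0.0285. None of these 6 kept its call with an estimated correlation (adjusted p = 0.24, 0.0805, 0.461, 0.24, 0.69 and 0.332 with an estimated correlation). Of their members, 1 of 14, 1 of 15, 0 of 17, 1 of 13, 0 of 16 and 0 of 14 rose over all genes tested, and 9, 7, 3, 3, 0 and 0 adjusted over the list alone. Ccr7, the receptor that guides cells into T cell zones, fell by 1.42 ± 0.39, and Prf1, the gene of perforin, rose by 3.31 ± 0.89.

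The largest single rises in Immature cells were Ubd, an interferon-inducible ubiquitin-like protein (chromosome 17, 37504783 to 37506992), from 0.103 ± 0.05 to 18.8 ± 15.7 CPM, and Madcam1, an adhesion ligand of lymphocytes (chromosome 10, 79500393 to 79504376), from 0.133 ± 0.11 to 24.6 ± 26.6 CPM. Csn2, a milk casein, rose by a log2 fold change of 6.37 ± 1.12, Hmgb1-ps3 by 5.73 ± 1.01, Thy1, a T cell surface protein, by 5.12 ± 1.07, and Serping1, the complement C1 inhibitor, by 4.65 ± 1.06. Immature_1Mek2 replicates 3 and 4 carried most of the rise of Ubd, Madcam1, Csn2 and Serping1, with 13.5 to 53.4 CPM. Replicate 2 stood at 0.973, 0.973, 0.461 and 1.18 CPM for these genes, but at 9.22 for Hmgb1-ps3 and 15.3 for Thy1. The largest falls were Mx2 (chromosome 16, 97337281 to 97362101), by 4.31 ± 0.83, and Oasl1, by 2.58 ± 0.57, both interferon-inducible antiviral genes, and Ccdc9 (2.74 ± 0.67), the peptide transporter Slc15a2 (2.72 ± 0.65), the collagen gene Col6a4 (2.29 ± 0.52) and Cpne4 (1.97 ± 0.46). The interferon response list as a whole was not called (adjusted p = 0.187; median -0.32).

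In all, 197 of 21115 genes passed in Immature cells, 171 up and 26 down. The count was 32 without Immature_1Mek2 replicate 3, 738 without replicate 2 and 549 without Immature_wt replicate 1. It was 50 in exon reads, 0 with a term for background reads on long neuronal genes (1420 at an unadjusted p under 0.05 with that edgeR term; without it limma voom gave 268 and DESeq2 287), 5 with the library of animal 565 added as 1Mek2 and 153 with it added as wt.

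**Figure D2:**
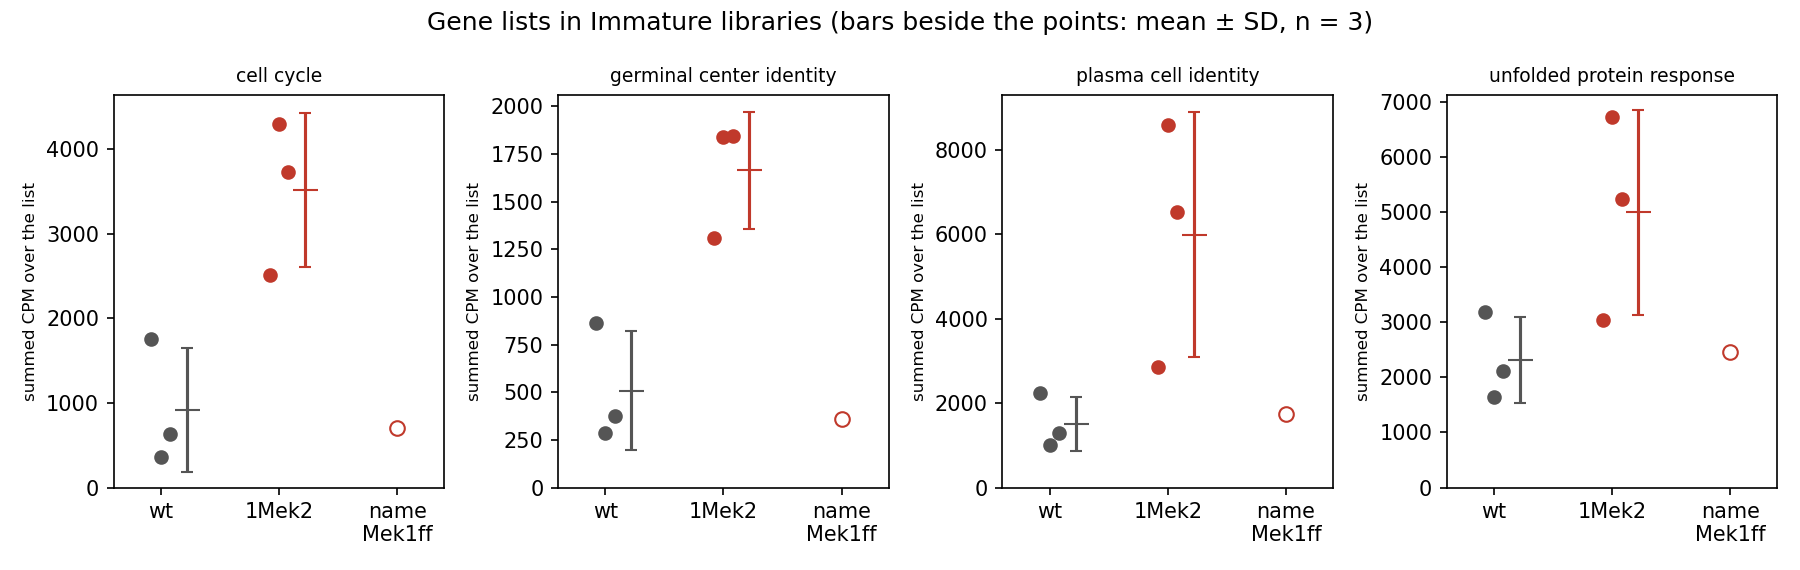
Summed CPM over each of 4 gene lists in single Immature libraries, with mean and SD (n = 3) beside the points; the open point is the library of animal 565, whose name reads Mek1ff. The sum of the cell cycle list ran from 360 to 1754 CPM in wt and from 2517 to 4304 in the libraries labelled 1Mek2, with 700.0 in the library of animal 565.

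In GC cells, 3 genes rose and 6 fell in the libraries labelled 1Mek2 (n = 4 and 4). Gadd45g, a growth-arrest and stress gene, rose from 15.2 ± 2.42 to 104 ± 30.9 CPM (chromosome 13, 52000711 to 52002511; adjusted p = 0.00846), Lifr, the receptor of leukemia inhibitory factor, by a log2 fold change of 4.13 ± 0.66, and Gatm, which makes the precursor of creatine, by 2.18 ± 0.37. The ion channel genes Trpm5 and Kcnk12 fell by 7.03 ± 1.17 and 5.05 ± 0.81, and Dlgap2, Thsd4, Arhgap6 and Etl4 by 2.75 ± 0.45, 2.69 ± 0.46, 2.59 ± 0.45 and 2.47 ± 0.44. Trpm5 stood at 40.03 CPM in GC_wt replicate 2 and between 1.41 and 8.58 in the other wt libraries. Glycolysis genes rose as a list (adjusted p = 6.30e-10; median 1.22), with Pkm at 468 ± 102 and 1329 ± 456 CPM and Eno1 at 322 ± 65.7 and 849 ± 296, though none of its 14 members passed over all genes (9 adjusted over the list alone). The lists of the unfolded protein response (5.69e-06), antigen presentation (1.00e-05), Myc targets (0.000413) and the cell cycle (0.00128) also rose, and marginal zone identity fell (0.026). None of these 6 was called with an estimated correlation (adjusted p = 0.265, 0.197, 0.438, 0.438, 0.702 and 0.414 with an estimated correlation). Members of these other lists that passed numbered 0 over all genes, and 3, 0, 0, 0 and 2 adjusted over the list alone.

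Of 16681 genes tested in GC, 9 passed with edgeR and 2017 had an unadjusted p under 0.05; limma voom called 0, DESeq2 142 and exon reads 0. With the background term edgeR called 0, so none of the 9 passed, though all kept their direction; the median of the genes with the longest span was -1.24. Leaving out GC_wt replicate 1 or 2 gave 0 genes, GC_wt replicate 4 gave 6, GC_1Mek2 replicate 1 gave 2, and GC_1Mek2 replicates 2, 3 and 4 gave 18, 16 and 16. Reads on long neuronal genes summed to 1276 ± 1223 CPM in wt and 278 ± 112 in libraries labelled 1Mek2 (exact permutation p = 0.371). Erythroid genes summed to 95.7 ± 66.7 and 27.4 ± 20.2 CPM (exact permutation p = 0.0571, and 0.0286 in exon reads). Sex-linked genes summed to 5.33 ± 2.30 and 1.29 ± 0.51 (exact permutation p = 0.0286). Immunoglobulin took 1.27 ± 0.13 and 1.72 ± 0.58% of exon reads (exact permutation p = 0.0857). Each had an adjusted p of 0.486. No GC library had more than 0.0777 exon CPM of Ddx3y, and Xist was at 0 in the counts, so the sex-linked sum does not show a difference of sex.

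In ABC cells no gene passed between genotypes, and antigen presentation genes gave the lowest list p. Of 16 such genes 13 had positive changes, with a median log2 fold change of 2.02, Cd74 at 1.35 and H2-Ab1 at 2.73; none passed over all genes, and 7 rose adjusted over the list alone. The lists of antigen presentation, the cell cycle and glycolysis rose (adjusted p = 0.00233, 0.00353 and 0.0036), though not with an estimated correlation (adjusted p = 0.456 with an estimated correlation in each). Cell cycle and glycolysis members rose in 0 and 2 cases adjusted over the list alone. In this comparison the genes of shortest span had a median of 1.86 and those of longest span -1.504. The list test takes no account of span, so the rise of these lists was not separated from that trend. Neutrophil genes summed to 0.15 ± 0.16 CPM in wt and 80.3 ± 75.4 in libraries labelled 1Mek2. The exon share was 67.3 ± 4.40 and 83.5 ± 6.06%, reads on long neuronal genes summed to 692 ± 395 and 126 ± 142 CPM, and immunoglobulin took 0.693 ± 0.27 and 1.33 ± 0.41% of exon reads (exact permutation p = 0.1 for each of these 4, adjusted 0.425). Plasmacytoid dendritic cell genes summed to 2764 ± 834 and 1458 ± 1729 CPM (exact permutation p = 0.3). edgeR called 0 of 12583 genes, with 2517 at an unadjusted p under 0.05; DESeq2 called 1445, limma voom 238, limma-trend on TPM 0, edgeR without the low-count filter 309 and edgeR on all libraries in 1 fit 5299. ABC_wt replicates 1 and 2 had reads on 18247 and 17008 genes, replicate 3 on 20206. Leaving out ABC_wt replicate 2 gave 21 genes and ABC_1Mek2 replicate 2 gave 30, and RLE scaling moved the median of all genes by -0.37 (log2).

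In Follicular cells, ERK feedback and target genes were lower in the libraries labelled 1Mek2 (n = 4 and 4). All 9 tested members had negative changes, with a median log2 fold change of -0.97. Dusp5, a phosphatase that switches ERK off, went from 5.95 ± 3.00 to 0.951 ± 0.69 CPM, Dusp4 from 3.84 ± 1.06 to 1.53 ± 0.72 and Dusp6 from 53.4 ± 71.7 to 19.4 ± 21.2. The feedback inhibitor Spry2 stood at -3.47 ± 0.86 and Spred2 at -0.73 ± 0.69. The list fell against all other genes (adjusted p = 3.00e-05), with 2 members passing adjusted over the list alone and 0 over all genes. It missed the threshold with an estimated correlation (adjusted p = 0.0545 with an estimated correlation). fry, which tests for any change of the list and not against other genes, gave an adjusted p of 0.00901. The same list also pointed down in Immature, GC, ABC, MarginalZone and Plasma without a call (adjusted p = 0.933, 0.177, 0.450, 0.575 and 0.172), and whether the effect differs between subsets was not tested for the list.

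**Figure D3:**
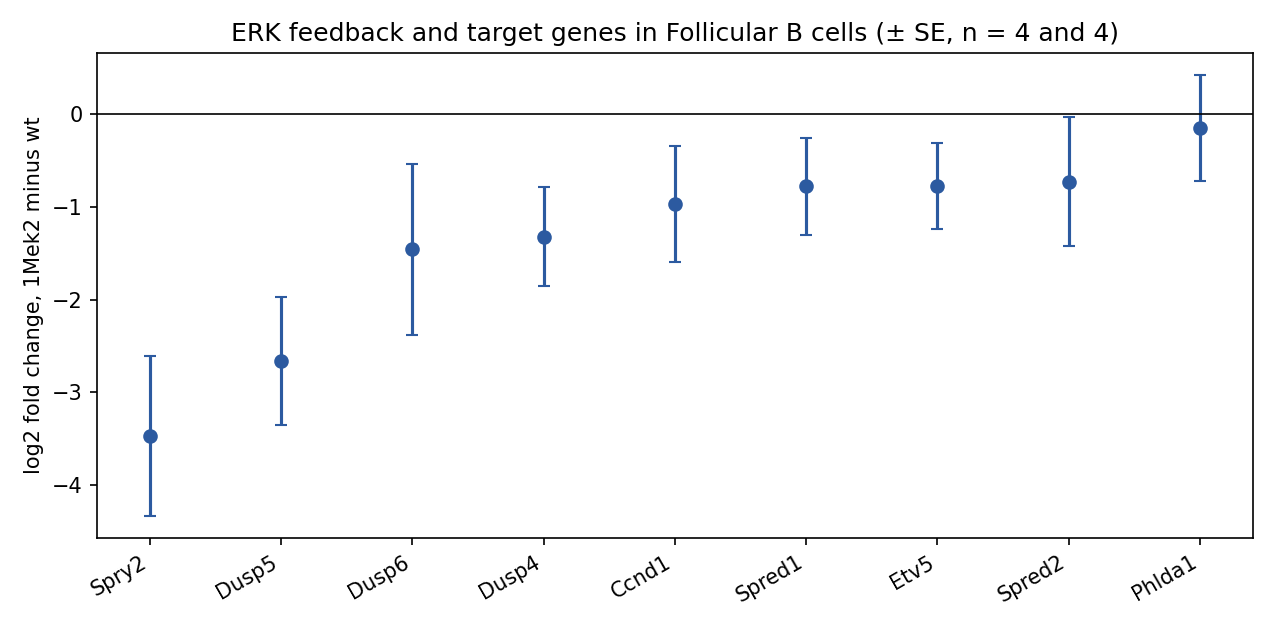
Log2 fold change of each tested member of the ERK feedback and target list in Follicular cells (libraries labelled 1Mek2 minus wt), with SE, n = 4 and 4. All 9 genes lie below 0, from Spry2 at -3.47 to Phlda1 at -0.15.

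Also in Follicular cells, antigen presentation genes rose as a list (adjusted p = 4.07e-06; 15 of 16 positive, Cd74 at 0.68 and H2-Ab1 at 0.85). Lists of Myc targets, the unfolded protein response, age-associated identity, glycolysis, plasma cell identity, the cell cycle and cholesterol synthesis rose, with adjusted p of 0.000726, 0.000824, 0.00112, 0.00112, 0.0193, 0.0277 and 0.0277. Immediate early genes (0.0231) and immature identity (0.0277) fell. None of these 10 was called with an estimated correlation (adjusted p = 0.224, 0.26, 0.425, 0.224, 0.425, 0.425, 0.622, 0.425, 0.26 and 0.425 with an estimated correlation, in the order given). No member passed over all genes; adjusted over the list alone, 3 Myc targets, 3 age-associated genes and 1 plasma cell gene rose and 1 immature gene fell. Natural killer cell genes summed to 14.0 ± 8.48 CPM in wt and 52.6 ± 32.4 in libraries labelled 1Mek2 (exact permutation p = 0.0286, adjusted 0.324). Neutrophil genes summed to 0.602 ± 0.72 and 23.2 ± 19.8 CPM, and reads on long neuronal genes to 37.6 ± 12.8 and 16.8 ± 4.37 (exact permutation p = 0.0571 for each, adjusted 0.324). edgeR called 0 of 14128 genes, with 1570 at an unadjusted p under 0.05; DESeq2 called 134, limma voom 0 and limma-trend on TPM 0. A term for library type gave 195 genes (120 up, 75 down), and leaving out Follicular_1Mek2 replicate 1 gave 14.

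In MarginalZone cells neither a gene nor a list passed between genotypes (n = 3 and 3). The unfolded protein response list came closest, with 13 of 16 members negative and a median log2 fold change of -0.67 (adjusted p = 0.101); Hsp90b1, the endoplasmic reticulum chaperone, stood at -1.28 and Pdia4 at -1.06. Cr2 stood at -0.10 and Cd74 at 0.86. Macrophage genes summed to 105 ± 43.6 CPM in wt and 305 ± 89.6 in libraries labelled 1Mek2, and neutrophil genes to 0.43 ± 0.35 and 77.9 ± 96.9 (exact permutation p = 0.1 for each). edgeR called 0 of 12907 genes, with 1132 at an unadjusted p under 0.05; DESeq2 called 201, limma voom 0 and limma-trend on TPM 0.

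In Plasma cells, 3 genes rose and 6 fell in the libraries labelled 1Mek2 (n = 3 and 3). Edn3, a peptide of the endothelin family (chromosome 2, 174602412 to 174625835), rose from 0.913 ± 0.33 to 53.1 ± 16.4 CPM, and the agouti gene a by a log2 fold change of 4.02 ± 0.39. Adgrl3, an adhesion receptor, fell by 4.96 ± 0.52, the ion channel gene Cnga1 by 3.94 ± 0.45, Igfbp4, which binds insulin-like growth factors, by 3.69 ± 0.42, Adam23 by 3.64 ± 0.44, the MHC class I gene H2-M2 by 3.30 ± 0.40 and Ube2e2 by 3.18 ± 0.36. Unfolded protein response genes and plasma cell identity genes rose as lists (adjusted p = 8.99e-06 and 1.32e-05; medians 1.43 and 0.99), with 0 members over all genes and 5 and 5 adjusted over the list alone. The cell cycle list rose (0.000879), and homing receptors (0.00388) and follicular identity (0.00728) fell. None of the 5 was called with an estimated correlation (adjusted p = 0.563, 0.563, 0.569, 0.398 and 0.398 with an estimated correlation); adjusted over the list alone, 1, 6 and 3 members of the last 3 passed. The immunoglobulin share of exon reads was 10.9 ± 3.48% in wt and 20.6 ± 4.19% in libraries labelled 1Mek2, and T cell genes summed to 5586 ± 2273 and 3495 ± 248 CPM (exact permutation p = 0.1 for each). On a scale over all libraries, the neutrophil gene Ngp had means of 1421 CPM in wt and 2773 in libraries labelled 1Mek2. S100a8 had 333 and 666, and Ltf 296 and 294. Leaving out any 1 of the 6 libraries gave 0 calls, as did exon reads. A term for library type gave 955 genes (631 up, 324 down), DESeq2 1080 and limma-trend on TPM 1120.

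The list of MAPK cascade genes, which holds both targeted genes, was not called in any subset (adjusted p from 0.191 to 0.822), nor was B cell receptor signalling (from 0.307 to 0.803) or interferon response (from 0.0509 to 0.815).

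Averaged over the 6 subsets, the 8 genes with the smallest p among those with a mean of at least 5 CPM and no provisional symbol were all higher in libraries labelled 1Mek2. Cdk2ap2 rose by a log2 fold change of 1.81 ± 0.21 (adjusted p = 9.70e-07), Eif5a, a translation factor, by 1.36 ± 0.16, Ftl1, the ferritin light chain, by 1.06 ± 0.13, Mrpl34, of the mitochondrial ribosome, by 2.38 ± 0.29, and Rnaseh2c, a subunit of ribonuclease H2, by 1.91 ± 0.25. Pianp rose by 5.48 ± 0.64, Gstt2, a glutathione transferase, by 2.30 ± 0.28 and Fxyd5 by 1.95 ± 0.25. In the tests within subsets ABC had the largest change in each: Cdk2ap2 5.85 (0.46 to 1.32 in the other subsets), Eif5a 3.41 (0.81 to 1.20), Ftl1 2.84 (0.34 to 1.12), Mrpl34 8.80 (0.81 to 1.504), Rnaseh2c 7.79 (0.10 to 1.65), Gstt2 7.24 (0.67 to 1.89), Fxyd5 6.56 (-0.02 to 1.99) and Pianp 8.82 (3.33 to 8.16, not tested in GC). Except for Pianp, the wt mean of each gene was lower in ABC than in every other subset. Rnaseh2c stood at 1.00 CPM in wt ABC against 36.8 to 117 in the others, and Mrpl34 at 0.551 against 22.3 to 74.8. A total of 1510 of 25181 genes passed, 1167 up and 343 down. Without the animal block edgeR gave 1479 up and 1373 down. The median change went from 0.33 in the fifth of genes with the shortest span (658 up, 22 down) to -0.45 in the fifth with the longest (18 up, 215 down). The exon share of gene-span reads was higher in libraries labelled 1Mek2 in every subset, from 88.9 against 87.6% in Plasma to 83.5 against 67.3% in ABC. The count was 719 without animal 358, 836 without animal 654 and 923 without animal 636, and 968 without ABC_wt replicates 1 and 2, which leaves 1 wt library in ABC. It was 835 in exon reads and 3340 with a term for library type.

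**Figure D4:**
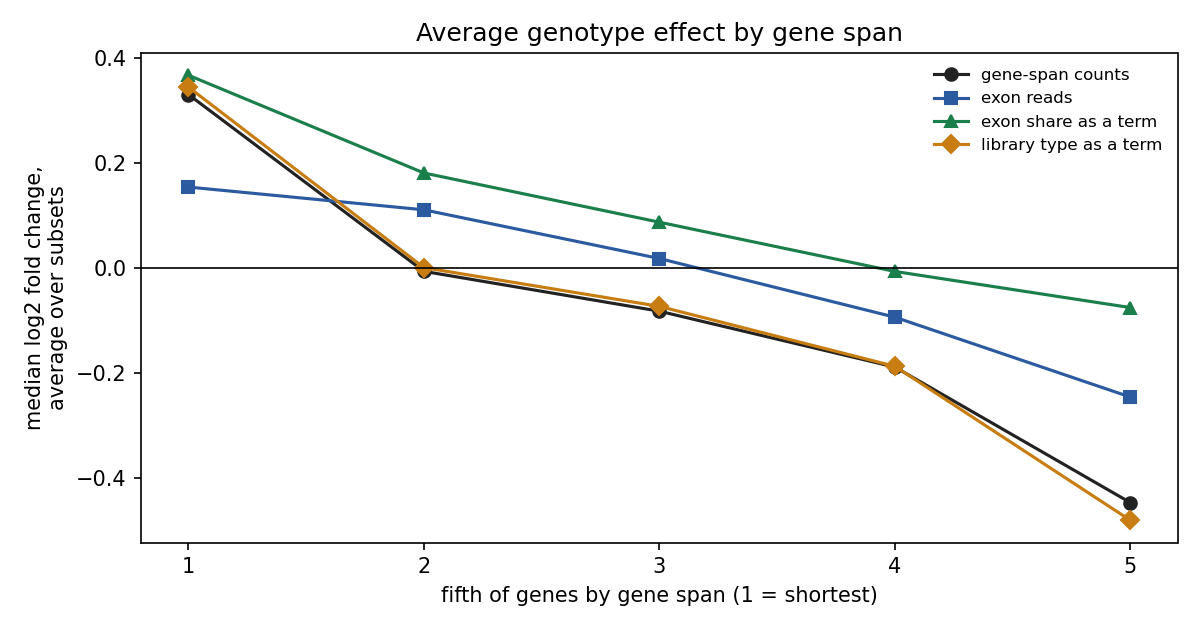
Median log2 fold change of the average genotype effect in 5 equal groups of genes by gene span (1 is the shortest), for gene-span counts, exon reads, and gene-span counts with the exon share or the library type of each library as a term. In gene-span counts the medians fell from 0.33 to -0.45, and in exon reads from 0.15 to -0.25.

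The interaction test asked whether genotype effects differ between subsets, and the genes with the smallest p differed in ABC. In wt, the ABC mean of each was below that of every other subset. On a scale over all libraries, Rnaseh2c stood at 1.00 CPM in wt ABC (36.8 to 117 in wt of the other subsets). Polr2g stood at 2.75 (124 to 386) and Psmd10 at 0.265 (34.7 to 83.5). In ABC libraries labelled 1Mek2 these genes stood at 218, 152 and 65.9. Rnaseh2c had a log2 fold change of 7.79 in ABC and between 0.10 and 1.65 in the other subsets (adjusted p = 3.58e-06), Polr2g, an RNA polymerase II subunit, 5.86 in ABC and -1.14 to 0.79 elsewhere, and Psmd10, of the proteasome, 7.99 and -0.54 to 0.61. Aurkaip1, Mrpl34, Yif1a, Txn2 and Cnpy2 had 6.88, 8.80, 7.57, 4.77 and 6.55 in ABC. In all, 503 genes passed without the animal as a block, and chance was not excluded (6 of 40 splits of the animals gave as many). With RLE size factors 908 passed, and with limma voom and the animal as a block 1144. Without ABC_wt replicates 1 and 2, 20 passed, where ABC has 1 wt library and the spread comes from the other groups; without animal 670 the count was 2032, without 412 it was 196, without 323 it was 251, without 358 it was 279, without 487 it was 303 and without 636 it was 331.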

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

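The tests of mixed cells, of exchanged labels and of other splits of the samples were chosen only after the results were seen, as was the requirement that a value lie beyond its spread before it excludes an explanation of the gene span, background or Map2k2 patterns, and the spread over libraries of the cell cycle median.

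In the average over subsets, short genes were higher and long genes lower in libraries labelled 1Mek2, with a gap of 0.78 (log2; jackknife SE over the 16 animals 0.272) between the medians of the shortest and the longest of 5 classes of genes by span. The subsets were uneven, with medians of 1.86 and -1.504 in ABC, 0.31 and -1.24 in GC, and 0.27 and 0.12 in MarginalZone, where the median of long genes was not below 0. With the library type as a term the gap was 0.83, which argues against the type as the whole cause. With the exon share of each library as a term the gap was 0.44, and in exon reads it was 0.40; both lay within 1 SE of 0.39, half-way to none, so neither a differing exon share nor counted intron reads can be told apart from an effect of genotype. Degraded or intron-rich RNA in some wt libraries may account for part of the gap, and an effect of the genotype on long genes stays open and untested.

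In Immature cells, cell cycle, plasma cell and germinal center genes were higher in libraries labelled 1Mek2. Germinal center cells among the sorted cells are argued against for the plasma cell genes, since 13 of 15 stood above their level in GC libraries labelled 1Mek2. For the cell cycle genes such cells stay open. Those genes needed a median GC share of 49.8% (36.0 to 65.2% over the genes) and the germinal center genes 26.3%. The latter ran from -3.18% for Bcl6, which did not rise, to 48.2% for Gna13, so the ranges overlap. The shares were also near each other, 29.0% and 20.4%, in replicate 2. Plasma cells, which the CD138-negative gate would remove, may account for part. A share of 11.5%, taken from the unfolded protein response genes, left 5 of 15 plasma cell genes more than 3-fold below the level it would bring. Most of them would have to lie so far below to argue against such cells. In exon reads Ighg1 went from 138 to 4183 CPM, Ighe from 2.94 to 210 and Jchain from 423 to 4060. For these genes every library labelled 1Mek2 stood above every wt library, though edgeR called none. Igha stood at 60.2 and 52.3. Class-switched cells among those sorted would bring such reads, but this was not tested. With the long-gene background as a term the median of the cell cycle genes went from 1.96 to 1.38 (jackknife SE over the 6 libraries 1.14 and 1.09) and all 24 genes stayed above 0; 1.38 lay within its SE of 0.98, 0.5 of the median without the term, so the background cannot be told apart from genotype, which stays open and untested; the calls went from 10 to 0 (median SE per gene 0.52 in both), for a reason not tested.

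Map2k2 was higher in the average over libraries labelled 1Mek2, while Map2k1 was lower without overlap in ABC alone (216 to 272 against 429 to 1256 CPM). With the exon share as a term the average log2 fold change of Map2k2 was 1.34 (1.10 without), which argues against the exon share as the whole cause. Map2k2 stood at percentile 96.9 of genes in its class of gene span, within its SE of the 95th percentile at 0.94, so the trend with gene span cannot be told apart. Exchanged labels may also apply: Map2k2 was lower in every library labelled wt in 3 subsets, and not without overlap in the others. Map2k1 in ABC ran as the labels say in gene-span counts. It spans 67822 bases, however, and the genes of longest span had a median of -1.504 in ABC. Its fall there lay within its SE of that median, so it does not bear on the labels. In exon reads Map2k1 stood at -1.73 ± 0.74 (log2) in MarginalZone, -0.56 ± 0.27 in Immature and 2.48 ± 1.60 in ABC. The ABC value rested mostly on 1 library, the only one of type 1 there. The genes point apart, which keeps this open. A response of the second kinase gene to loss of the first was not tested.

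Animal 565, whose Immature library is labelled 1Mek2 and whose GC library is labelled wt, was nearer to wt in its Immature library for 163 of the 197 genes called there and nearer to 1Mek2 for 34.

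Of 115 tests for a single library far from the others of its group of 4, 13 found one, where chance gives about 5%. Neutrophil genes summed to 316 CPM in Immature_1Mek2 replicate 2 (0.524 to 3.28 in the others of its group), 23.6 in GC_wt replicate 4 (0.316 to 2.66) and 1.83 in Follicular_wt replicate 1 (0.183 to 0.332), on a scale over all libraries. Trpm5 was at 33.8 CPM in GC_wt replicate 2 (1.39 to 6.77). GC_1Mek2 replicate 4 had 2.58% of exon reads on immunoglobulin genes (1.39 to 1.497), 79.7 CPM of plasmacytoid dendritic cell genes (36.9 to 41.3) and 79.6 CPM of basophil and mast cell genes (0.290 to 1.39). Natural killer cell genes summed to 18.9 CPM in GC_1Mek2 replicate 3 (10.3 to 11.6). Follicular_wt replicate 4, of library type 1, had an exon share of 87.8% (66.9 to 68.9) and 68.1 CPM of plasmacytoid dendritic cell genes (159 to 163). In Follicular_1Mek2, replicate 2 had 1.79% of exon reads on immunoglobulin genes (1.501 to 1.53), replicate 1 had 418 CPM of erythroid genes (41.1 to 55.5) and replicate 3 had 6.60 CPM of basophil and mast cell genes (0 to 0.348).

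By the interaction test 503 genes passed; 20 passed without ABC_wt replicates 1 and 2, a fit with 1 wt library in ABC, and chance was not excluded (6 of 40 splits of the animals gave as many, up to 1897). The smallest adjusted p were those of Rnaseh2c (3.58e-06), Polr2g, Aurkaip1 and Psmd10 (2.08e-05 each), Mrpl34 (2.27e-05), Yif1a (2.88e-05), Txn2 (3.83e-05) and Cnpy2 (4.97e-05).

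Exon reads held signal that the gene-span counts lack: 1849 genes were at 0 in every count column with a mean of at least 10 exon reads. Ighg1, the constant gene of IgG1, had exon CPM (mean ± SD) in libraries labelled 1Mek2 of 4183 ± 1525 in Immature (138 ± 202 in wt) and 2121 ± 672 in GC (650 ± 171). It stood at 385 ± 548 in ABC (5.35 ± 3.32), 77.8 ± 98.8 in Follicular (5.52 ± 4.67), 225 ± 345 in MarginalZone (6.14 ± 6.98) and 18320 ± 5616 in Plasma (1794 ± 833). In Follicular and in MarginalZone 1 library labelled 1Mek2 was below every wt library. In exon reads edgeR called Ighg1 in no subset (adjusted p from 0.0679 to 0.592). With the library type as a term it was called in Plasma (0.00153).

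Other splits of the libraries argued against chance for GC against Follicular (3923 genes, highest other split 0) and for the average (1508 and 446, with the animal correlation held). For Immature against Follicular (7938 and 7815) and for the lists in Follicular (11 and 10) the margin was narrow. Those 11 lists were called at the preset correlation, and 0 with an estimated correlation. In each of these results 1 split, the real one, gave as many. For ABC (2903 and 34) and MarginalZone (50 and 31) against Follicular 1 of 35 splits, the real one, gave as many, but the groups share 3 and 2 animals, which free splits ignore. Only 8 and 12 splits part as many shared animals as the real one, too few for a share under 0.05; the highest other among them was 0 in both. The split with 7815 parts Follicular_wt replicates 1 to 3, of type 2, from the rest. A split by library type thus gave nearly as many genes, and the 7938 cannot be credited to the subset alone. For GC, no split of 4 against 4 can part Follicular_wt replicates 1 to 3 from all others. The splits thus do not weigh the library type there. The GC libraries lay nearer to type 1 than to type 2 on the index of genes that set the types. The 3923 genes therefore cannot be credited to the subset alone either. Chance was not excluded for the GC genotype effect (9 and 43; 2 of 35 splits gave as many), the Follicular genotype effect (0 and 1; 35 of 35), Plasma against Follicular, which share 1 animal (2754 and 2762; 2 of 35), the GC lists (6 and 10; 23 of 35) and the interaction (503 and 1897; 6 of 40). The split with 2762 also parts Follicular_wt replicates 1 to 3 from the rest; with the library type as a term the real count was 3158.

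With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and the highest other values were 197 and 43 for Immature, 0 and 1 for ABC, 0 and 4 for MarginalZone and 9 and 458 for Plasma. For the lists they were 10 and 15 in Immature (5 splits gave as many), 3 and 5 in ABC, 0 and 3 in MarginalZone and 5 and 4 in Plasma. The Plasma split with 458 follows the library type exactly and points to a structure of the samples; with the type as a term the genotype effect gave 955 genes.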

How the results depend on the processing

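Alternatives with exon reads, a term for library type, background or exon share, single library types, and without ABC_wt replicates 1 and 2 together were chosen only after seeing the data. So were, for the gene lists, leaving out single libraries and placing animal 565 in either group. The others were fixed before the data were examined. The cause of the changes below was not tested unless stated.

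No gene named by the rule and no list changed direction past the threshold under any alternative. Among all called genes some did change direction. Exon reads kept the direction of 2586 of 2699 called genes tested for Immature against Follicular, and of 2223 of 2377 for ABC against Follicular. Of the called genes named in the text, 1316 comparisons with an alternative stayed past the threshold and 469 did not. Of the genes not called, 6565 stayed on their side, 157 passed under an alternative and 684 moved in value. Of list comparisons 404 stayed past the threshold and 154 did not. Of counts 200 stayed within 1.5 times and 135 moved beyond, and of sums 71 stayed and 7 moved.

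Without the low-count filter the counts were 344 in Immature (197 with it), 42 in GC (9), 309 in ABC (0), 2 in Follicular (0), 207 in MarginalZone (0) and 454 in Plasma (9), and against Follicular 18109 in Immature, 13141 in GC and 108 in MarginalZone. A filter at 1 CPM gave 116 in Immature. RLE size factors gave 297 in Immature and 908 for the interaction. DESeq2 gave 142 in GC, 1445 in ABC, 134 in Follicular, 201 in MarginalZone and 1080 in Plasma, and against Follicular 5342 in ABC and 501 in MarginalZone. limma voom gave 0 in GC and 238 in ABC, and limma-trend on TPM 59 in Immature and 1120 in Plasma. A fit on all libraries together gave 0 in Immature, 0 in GC, 5299 in ABC, 1 in MarginalZone and 0 in Plasma. edgeR without the animal block gave 2852 for the average, and limma voom with it 1144 for the interaction.

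Exon reads gave 50 in Immature, 0 in GC and 0 in Plasma, 999, 2573 and 15 for Immature, GC and MarginalZone against Follicular, and 835 for the average. The term for library type gave 3 in ABC, 195 in Follicular, 955 in Plasma, 263 for MarginalZone against Follicular and 3340 for the average; together with exon reads it gave 1 in ABC, 9 in Follicular and 973 in Plasma. The background term gave 0 in Immature and 0 in GC, and with exon reads 1 and 0. Adding animal 565 to 1Mek2 gave 5 in Immature. Type 2 libraries gave 1363 for ABC against Follicular, and the Follicular library of type 1 alone 431 for GC against Follicular, where it is assumed to vary like the GC libraries. Without ABC_wt replicates 1 and 2 together, which leaves 1 wt library in ABC with its spread taken from other groups, the average gave 968 and the interaction 20.

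The replicate numbers join libraries of the same animal in each of 3 pairs for ABC against Follicular and in 1 of 3 for MarginalZone against Follicular. For ABC the 3 pairs had correlations from -0.0827 to 0.0833 and the block by number or by animal gave 1206 in place of 2903. Animals were shared by 2 pairs for MarginalZone against Follicular (0.394 and 0.412), where the animal block gave 116 in place of 50, and by 1 pair for Plasma against Follicular. In the genotype comparisons the numbers join different animals; a block on them gave 1006 in Immature, 1 in GC and 0 in Plasma.

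Called lists fell with an estimated correlation from 10 to 0 in Immature, from 6 to 0 in GC, from 3 to 0 in ABC, from 11 to 0 in Follicular and from 5 to 0 in Plasma, and against Follicular from 7 to 0 in Immature, from 9 to 2 in GC, from 4 to 0 in ABC, from 6 to 1 in MarginalZone and from 9 to 3 in Plasma. fry, which tests for any change of a list and not against other genes, called 1 in Immature, 0 in GC, 0 in ABC, 1 in Follicular and 0 in Plasma, and 4, 9 and 15 for Immature, ABC and Plasma against Follicular. In ABC the replicate block gave 5 lists, type 2 libraries 5, exon reads 1 and exon reads with the type term 1. In MarginalZone the type term, exon reads with it and type 2 libraries gave 1 list each, and in GC exon reads with the background term gave 3.

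Leaving out single libraries gave 32 (without Immature_1Mek2 replicate 3) to 738 (without replicate 2) in Immature, 0 (GC_wt replicate 1) to 18 (GC_1Mek2 replicate 2) in GC, 0 to 30 (ABC_1Mek2 replicate 2) in ABC, 0 to 14 (Follicular_1Mek2 replicate 1) in Follicular, 0 to 0 in MarginalZone and 0 to 0 in Plasma. Against Follicular it gave 6834 to 11680 in Immature, 3053 to 7025 (Follicular_wt replicate 4) in GC, 927 (Follicular_wt replicate 1) to 6427 (ABC_wt replicate 3) in ABC, 11 (Follicular_wt replicate 2) to 63 in MarginalZone and 1859 to 4616 (Follicular_wt replicate 4) in Plasma. Leaving out animals gave 719 (358) to 2088 (670) for the average and 196 (412) to 2032 (670) for the interaction. List counts ran from 9 to 11 in Immature, 6 to 12 (GC_wt replicate 3) in GC, 3 to 6 (ABC_wt replicate 1) in ABC, 5 (Follicular_1Mek2 replicate 2) to 13 in Follicular, 0 to 1 in MarginalZone and 5 to 6 in Plasma.

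Leaving out immunoglobulin genes was void, because nearly all of them are at 0 in the count table. At the fitted dispersions the tests on simulated data recovered 51% of 4-fold changes in Immature, 51% in GC and 38% in Follicular, and 0 to 2% in the other subsets, so a 4-fold change was often not detectable there.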

Other observations

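The genes below were chosen, and the tests on them made, only after their values were seen.

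Some class-switched antibody genes were higher in libraries labelled 1Mek2 in exon reads averaged over the subsets, though not in every subset. Ighg1 and Ighe, the constant genes of IgG1 and IgE, were higher by a log2 fold change of 3.63 ± 0.60 and 4.03 ± 0.67 (limma, adjusted p = 0.000332 for each). Ighg3 was higher by 1.75 ± 0.35 (0.00173), Ighg2b by 2.16 ± 0.46 (0.00352), Jchain by 1.53 ± 0.40 (0.0207) and Igkc, the kappa light chain, by 0.44 ± 0.12 (0.0239). Ighm and Ighd, of unswitched cells, stood at 0.03 and 0.10, Igha at -0.55 and Ighg2c at 1.55, without a call. Every library labelled 1Mek2 had more Ighg1 than every wt library in Immature, GC, ABC and Plasma. Ighg2b, Ighg2c and Ighg3 had positive log2 fold changes in Immature, ABC, Follicular and Plasma (edgeR on exon reads). In GC they stood at 0.01 ± 0.25, -0.36 ± 0.30 and -0.98 ± 0.30, and in MarginalZone at -0.55 ± 1.00, 1.29 ± 1.55 and -0.17 ± 0.77.

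Genes of neutrophil granules were also higher in the average: Ngp by 4.16 ± 0.90 (adjusted p = 0.00285), Camp by 3.52 ± 0.76 (0.00294), S100a8 by 3.54 ± 0.86 (0.00814) and S100a9 by 2.99 ± 0.75 (0.0106), while Ltf at 1.83 ± 0.61 was not called (0.0671). Interferon-inducible genes of 1 cluster on chromosome 1 were lower, with Mndal at -2.62 ± 0.39 (2.44e-05), Ifi208 at -2.20 ± 0.35, Ifi211 at -2.30 ± 0.46, Ifi204 at -1.84 ± 0.42 and Ifi203 at -1.08 ± 0.24; Ifi202b, Ifi205, Ifi206, Ifi207, Ifi209, Ifi213 and Ifi214 of the same cluster were not called. The peptide transporter gene Slc15a2 was lower at -2.68 ± 0.54 (adjusted p = 0.0014).

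Sva (chromosome 6, 42015328 to 42019785) ran from 0 to 0.105 CPM in 19 wt libraries of 7 animals and from 1.62 to 8.35 in 17 libraries labelled 1Mek2 of 7 animals. It was at 0 in the 3 libraries of animal 634, labelled 1Mek2, and at 0.0288 and 0.243 in the 2 libraries of animal 565. By Sva alone animal 634 stood with the wt animals. Sva was chosen after its values were seen and is not on the chromosome of Map2k1 or Map2k2. It therefore cannot test the label of animal 634, which stays in doubt. Map2k2 of this animal went the other way and stood above every wt library of the subset. It was at 545 CPM in ABC (wt at most 183), 329 in Follicular (147) and 269 in MarginalZone (137). The ABC, Follicular and MarginalZone libraries of animal 634 were kept as 1Mek2, and without this animal the average gave 1871 genes.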
